A study of Homo sapiens with 6 samples.

How the data were processed

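Total RNA from SUDHL-1 cells was the input for biotin labelling. The authors hybridised the labelled samples to 6 Affymetrix U133 Plus 2.0 arrays, 3 from cells given solvent and 3 from cells given CEP-14083 for 6 h. Per the labels, treatments were done in triplicate. Whether the 3 arrays of a group come from separate cultures is stated no further than that, and the p-values measure the spread between these arrays. The deposited values were intensity signals per probe set made by the authors with MAS5, on a linear scale, and the submitters' processing notes name MAS5 and Partek without versions. The values showed that each array had been scaled to a 2% trimmed mean of 150. Detection calls, scan dates and batches were not used here, so the signal alone served to judge which genes were measured well.

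The table held 54675 probe sets, of which 62 were Affymetrix controls. A platform annotation gave exactly 1 gene symbol to 41091 probe sets, several to 1801 and none to 11721. Of the probe sets with 1 symbol, 41037 matched a current gene record by Entrez gene ID, and 0 symbols changed. Arrays give hybridisation signals and not counts, so no depth applies, and the number of arrays limits the precision. No genome was used and no positions are given.

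Signals were transformed to log2(signal + 1), because the lowest signal was 0. Fold changes are on that scale, which understates the change of weakly expressed genes. Probe sets were kept when their mean over the 6 arrays reached the median of all probe sets (log2 of 4.466, a signal of 21.1), which left 27281, of which 22209 had 1 symbol. Each gene was represented by its probe set with the highest mean, giving 11531 genes. In 16 of the genes that passed, another probe set of the same gene passed with the opposite sign. The values were not normalised again. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided; files were read with the package data.table, version 1.17.8), and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. "Rose" and "fell" are used of genes past that threshold. On simulated data with the same number of genes, the fit recovered 49.3%, 80.6% and 92.4% of genes shifted by 0.5, 1 and 2 on the log2 scale, and 7 of 155 calls (4.52%) were false. The simulated genes were independent, with normal errors of the spread the fit had estimated. These shares therefore do not measure false calls on the real arrays.

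The tests, the 29 gene lists with their 516 genes and the rule for named genes were fixed before the data were examined. Of the list genes, 43 had no probe set with 1 symbol. The 24 pathway lists covered ERK output and feedback, STAT3 and STAT5 targets, genes associated with NPM-ALK, MYC targets and ribosome biogenesis, G1/S and DNA replication, G2/M and mitosis, G1 cyclins and CDK inhibitors, FOXO targets, glycolysis, hypoxia, cholesterol synthesis, ATF4 and amino acid response, unfolded protein response, heat shock proteins, interferon response, T cell receptor and T lineage, cytotoxic and activation molecules, cytokines and chemokines, cytokine receptors, apoptosis, p53 targets, NF-kB targets, DNA methylation and Polycomb, and MHC class II. The 5 marker lists covered B cells, myeloid cells, erythroid cells, fibroblasts and epithelium. The 24 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over those lists. Camera called 12 lists, 9 down and 3 up; with the correlation estimated for each list only the ERK list was called. A second test, fry, which asks whether the members of a list move one way on balance and does not compare them with other genes, called 16. In data simulated with independent genes, a list shifted by 0.5 was called, and 0 of 20 unshifted lists were. Genes correlated within a list were not simulated, so this does not test the preset correlation.

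Genes were named by rule: ALK and NPM1; the 6 largest rises and the 6 largest falls among genes past the threshold whose groups did not overlap; up to 4 members of smallest adjusted p of each list called by camera and up to 2 of each other list; and, where no member passed, the 2 of largest absolute change, as values. Together the list and ranking rules named 83 genes.

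RNA quality was measured as the log2 ratio of 3' to 5' control probe sets and compared with exact permutation tests. Arrays were also checked for duplicates, of which there were 0, for outlying arrays and for pairing by number.

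Alternatives fixed before the data were examined were quantile normalisation, arrays centred on their medians over all probe sets, no filter and a stricter filter, pseudocounts of 16 and 64, the median of a gene's probe sets, the removal of less specific probe sets (suffixes x, s and a), eBayes without the trend, no variance moderation, a replicate block, each array left out in turn, camera with an estimated correlation and fry. A further 2 scalings were chosen after solvent control 3 was seen to differ at low signals: arrays centred on their medians over the tested genes, and cyclic loess.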

Results

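Transcript levels were measured in SUDHL-1, an established line of anaplastic large T cell lymphoma that expresses the ALK kinase fused to nucleophosmin (NPM-ALK). Cells received the ALK inhibitor CEP-14083 or its solvent for 6 h, with 3 arrays in each group. The deposited values were MAS5 signals in arbitrary intensity units for 54675 probe sets of an Affymetrix U133 Plus 2.0 array, and the 2% trimmed mean was 150 on every array. Median signals lay between 21 and 24.5 on 5 arrays and at 37.2 on solvent control 3, where the weak probe sets read higher. The number of arrays limits the precision of every value given here. The comparison asked which transcripts differed between cells with and without 6 h of CEP-14083. It held a single compound, and no measure of ALK activity was analysed here. Effects of ALK inhibition therefore cannot be told apart from other effects of the compound.

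After 6 h of CEP-14083, transcripts of genes induced by the ERK pathway and by STAT3 and STAT5, of ribosome biogenesis genes and of cytokine receptors were lower than in solvent, and transcripts of mitosis genes were higher. Of these lists only that of the ERK pathway stayed called with an estimated correlation between genes (adjusted p = 0.0171, against 0.0688 for STAT targets, 0.0797 for MYC targets and ribosome biogenesis, 0.0801 for cytokine receptors and 0.14 for G2/M). MYC, the transcription factor that drives growth and ribosome production, fell from a signal of 5005 ± 81.3 to 116 ± 3.46 (SD, n = 3 each; log2 fold change -5.41, SE 0.0748, limma adjusted p = 2e-13). SOCS3, the suppressor of cytokine signalling induced by STAT3, fell from 4748 ± 213 to 102 ± 8.50 (log2 fold change -5.52, SE 0.0867, adjusted p = 4.7e-13; -4.75 with the median of its probe sets). In the other direction, TXNIP, a thioredoxin-binding protein that restrains glucose uptake, rose from 226 ± 19.4 to 2407 ± 23.8 (log2 fold change 3.41, SE 0.0849, adjusted p = 2.9e-11).

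Of 11531 genes tested with limma, 4381 (38%) passed a Benjamini-Hochberg adjusted p of 0.05, of which 2706 rose and 1675 fell. At least 2-fold changes were seen in 899 genes, of which 414 rose and 485 fell. Changes of at least 8-fold numbered 6 rises and 35 falls. The balance between rising and falling genes depended on the scaling of the arrays. After each array was centred on its median over the tested genes, a scaling chosen after seeing the data, 1977 genes rose and 2187 fell. With each array centred instead on its median over all probe sets, which raised the median log2 fold change of the tested genes from 0.096 to 0.227, 1375 genes passed, 908 rising and 467 falling. The centring moved every log2 fold change by 0.131 and raised the median SE from 0.135 to 0.331. Of the 83 genes named by rule, 20 kept their direction but no longer passed with it: CDT1, DNAJB1, FCER1G, GBP1, GZMA, GZMB, HK1, HSPB1, IFIH1, IL26, KRT18, LEF1, MCL1, MCM5, NFKBIA, PFKP, S100A8, SESN2, SUZ12 and XBP1.

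**Figure D1:**
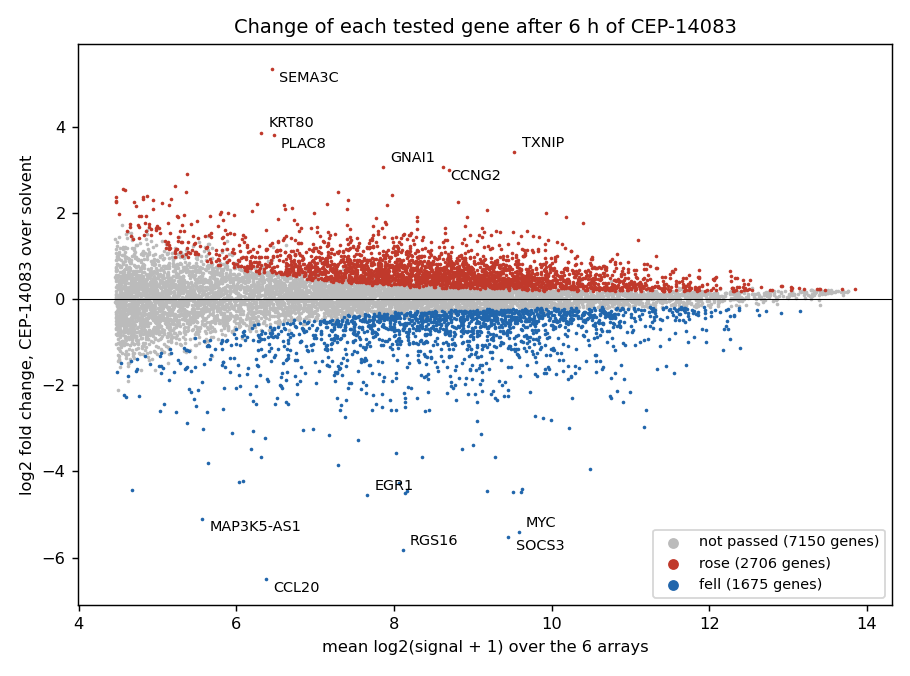
Log2 fold change of each of the 11531 tested genes, CEP-14083 over solvent (vertical axis), against its mean log2(signal + 1) over the 6 arrays (horizontal axis). Each point is a gene, red for the 2706 that rose, blue for the 1675 that fell and grey for those that did not pass; the 6 largest rises and the 6 largest falls among genes whose groups did not overlap are named, and the falls reach -6.50 while the rises reach 5.32.

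At a pseudocount of 1, the 6 largest rises among genes whose groups did not overlap were in SEMA3C, KRT80, PLAC8, TXNIP, CCNG2 and GNAI1. With a pseudocount of 64 the order was TXNIP (3.09), SEMA3C (3.00), CCNG2 (2.59), RNA45SN5 (2.53), GNAI1 (2.36) and PLAC8 (2.14), with KRT80 (2.02) next. SEMA3C, a secreted semaphorin, rose from 12.97 ± 2.79 to 552 ± 34.0 (SD, n = 3 each; log2 fold change 5.32, SE 0.213, adjusted p = 2.3e-09; 3.38 with the median of its probe sets). KRT80, a type II keratin, rose from 28.5 ± 22.8 to 303 ± 21.4 (log2 fold change 3.86, SE 0.585, adjusted p = 0.00021). Its log2 fold change was 2.92 without solvent control 2 and 4.50 without solvent control 3, and its adjusted p was 0.0566 without variance moderation, the highest over its alternatives, whose lowest was 2e-30. PLAC8 rose from 26.1 ± 14.0 to 330 ± 14.5, a log2 fold change of 3.79 (SE 0.369). CCNG2, the cyclin G2 linked to cell cycle arrest, rose from 137 ± 29.9 to 1140 ± 68.4, by 3.06 (SE 0.135) on the log2 scale. GNAI1, an inhibitory G protein subunit, rose from 79.8 ± 4.90 to 673.5 ± 15.1, by 3.06 (SE 0.113).

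The 6 largest falls under the same rule, also at a pseudocount of 1, were in CCL20, RGS16, SOCS3, MYC, MAP3K5-AS1 and EGR1. CCL20, a chemokine that attracts CCR6-bearing lymphocytes, went from 794 ± 108 to 8.67 ± 5.67 (SD, n = 3 each; log2 fold change -6.50, SE 0.329, adjusted p = 1.6e-08). RGS16, a regulator of G protein signalling, went from 2089 ± 181 to 37.1 ± 12.2 (log2 fold change -5.83, SE 0.198, adjusted p = 5e-10). The probe set assigned by Entrez gene ID to the antisense transcript MAP3K5-AS1 went from 278 ± 43.0 to 7.73 ± 4.24 (log2 fold change -5.09, SE 0.373). EGR1, an immediate early transcription factor, went from 981 ± 33.1 to 41.6 ± 9.87 (log2 fold change -4.55, SE 0.158). The size and order of falls to near the floor of the array depend on the pseudocount. With a pseudocount of 64 the 6 largest falls were in SOCS3 (-4.85), MYC (-4.81), RGS16 (-4.42), GPR84 (-4.04), CEMIP (-4.01) and PLAUR (-3.98), and the log2 fold change was -3.56 for CCL20, -3.31 for EGR1 and -2.25 for MAP3K5-AS1.

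**Figure D2:**
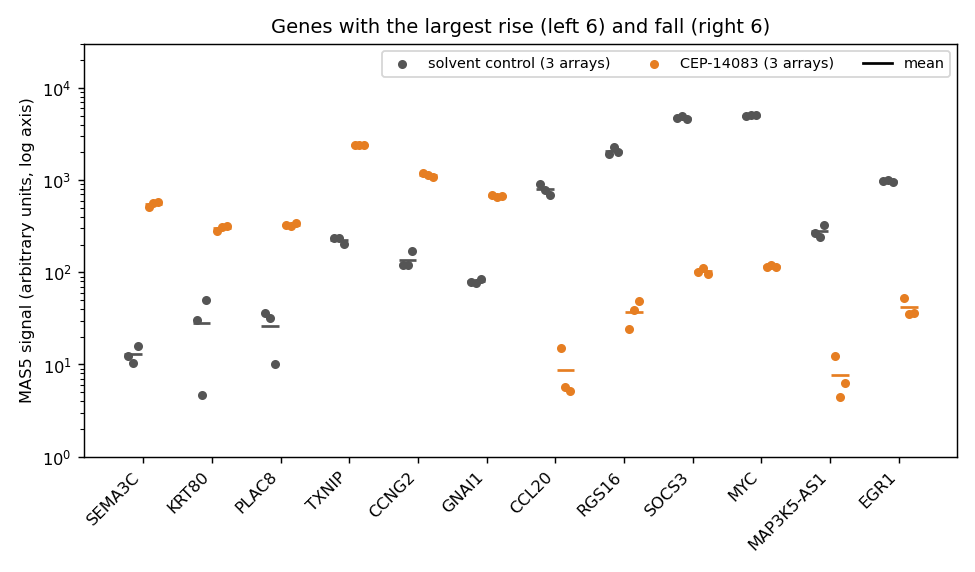
MAS5 signal in arbitrary units (vertical log axis) of the 6 genes with the largest rise and the 6 with the largest fall, with a grey point for each of the 3 solvent arrays, an orange point for each of the 3 CEP-14083 arrays and a bar at each group mean. The 3 CEP-14083 values of each gene lie wholly above or wholly below its 3 solvent values, and the lowest group means are 7.73 for MAP3K5-AS1 and 8.67 for CCL20.

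The transcripts of the drug's target were measured as well, since CEP-14083 acts on the kinase and not on its messenger RNA. The ALK probe sets read 2627 ± 126 in solvent and 2642 ± 54.0 with CEP-14083 (SD, n = 3 each; log2 fold change 0.01, SE 0.0734, adjusted p = 0.969), and 5028 ± 290 and 5426 ± 286 (0.11, SE 0.074, adjusted p = 0.444). The 3 probe sets of NPM1, which encodes the nucleophosmin part of the fusion, had log2 fold changes of 0.15, 0.14 and 0.14 with adjusted p of 0.23, 0.381 and 0.283. Which part of the NPM1 signal came from the fusion transcript and which from normal NPM1 was not examined. No probe set of ALK or NPM1 passed the threshold. These adjusted p-values are over all probe sets other than the Affymetrix controls, with no filter.

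Genes induced by the ERK pathway, together with the feedback inhibitors that ERK itself induces, were called downward. Of 19 tested members, 18 fell, 0 rose and 1 did not pass, and 19 fell when adjusted over the list alone. Their median log2 fold change was -2.29 (camera adjusted p = 8.4e-21; adjusted p = 0.0171 with an estimated correlation). The list median lay within -2.4 to -1.5 over all alternatives. DUSP6, the phosphatase that inactivates ERK, fell from 1345 ± 43.6 to 59.2 ± 10.7 (SD, n = 3 each; log2 fold change -4.50, SE 0.13). PLAUR, the urokinase receptor, fell from 3647 ± 167 to 171 ± 14.7 (-4.41, SE 0.0859, and -1.16 without less specific probe sets). IER2, an immediate early gene like EGR1, fell from 4376 ± 193 to 836 ± 64.2 (-2.39, SE 0.0762).

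Targets of STAT3 and STAT5 formed the next group. Of the 26 tested, 19 fell, 0 rose and 7 did not pass, with 19 falling when adjusted over the list alone. Their median log2 fold change was -1.05 (camera adjusted p = 8.8e-17; adjusted p = 0.0688 with an estimated correlation). CD274, which encodes the immune checkpoint ligand PD-L1, fell from 1344 ± 105 to 60.7 ± 12.4 (SD, n = 3 each; log2 fold change -4.46, SE 0.141, and -3.51 with the median of its probe sets). SOCS1, an inhibitor of JAK kinases, fell from 1179 ± 204 to 90.5 ± 3.02 (-3.68, SE 0.126, and -2.03 with the median of its probe sets). MYC and SOCS3 are members of this list too.

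Genes that general knowledge links to NPM-ALK were tested as a list of their own, which shares 7 members with the STAT list. That list draws partly on work in such cell lines, so its direction is not independent evidence. The same holds for the 7 shared members, CD274 among them, where they count in the STAT list. Among its 23 tested members, 13 fell, 2 rose and 8 did not pass, and adjusted over the list alone 15 fell and 2 rose. Across the list, the median log2 fold change was -0.93 (camera adjusted p = 3.8e-10; adjusted p = 0.0797 with an estimated correlation). That median lay within -1.72 to -0.797 over all alternatives. TNFRSF8, which encodes the lymphoma marker CD30, fell from 1652 ± 83.1 to 158 ± 14.6 (SD, n = 3 each; log2 fold change -3.38, SE 0.0954). BCL2A1, an anti-apoptotic relative of BCL2, fell from 3368 ± 337 to 422 ± 38.6 (-2.99, SE 0.093). CD274 and PRF1 are members of this list too.

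The list of MYC targets and ribosome biogenesis genes was called downward. In this list 18 of 22 tested members fell, 0 rose and 4 did not pass, and 19 fell when adjusted over the list alone. Its median log2 fold change was -0.69 (camera adjusted p = 1.3e-12; adjusted p = 0.0797 with an estimated correlation). NOP16 and NOP2, nucleolar proteins of large ribosomal subunit assembly, fell by 1.63 (SE 0.0769) and by 1.31 (SE 0.0769) on the log2 scale. POLR1B, a core subunit of RNA polymerase I, fell from 1208.5 ± 144 to 401 ± 14.0 (SD, n = 3 each; -1.58, SE 0.0945). LYAR, a nucleolar protein, fell by 1.25 (SE 0.0792).

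The list of G2, M phase and mitosis genes was called upward. All 25 tested members rose, 25 rose when adjusted over the list alone, and the median log2 fold change was 0.81 (camera adjusted p = 1.4e-13; adjusted p = 0.14 with an estimated correlation). Without solvent control 3, the array with raised weak signals, the median was 0.75. CDC25C, the phosphatase that activates CDK1 at mitotic entry, rose from 178 ± 15.7 to 554 ± 34.5 (SD, n = 3 each; log2 fold change 1.63, SE 0.109). CENPE and KIF20A, mitotic kinesins, rose by 1.64 (SE 0.133) and 1.43 (SE 0.0996), and NUSAP1, a spindle protein, rose by 1.00 (SE 0.0702).

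The G1/S and DNA replication list was called upward as well. Of 26 tested members, 10 rose, 2 fell and 14 did not pass, and adjusted over the list alone 14 rose and 2 fell. The list median was 0.23 on the log2 scale (camera adjusted p = 0.0179; adjusted p = 0.373 with an estimated correlation). The camera adjusted p was 0.0541 without solvent control 3, 0.117 with arrays centred on their medians and 0.0502 with the stricter filter, within a range of 0.00026 to 0.373 over all alternatives. E2F2, a transcription factor of the S phase program, rose from 128 ± 30.2 to 438.5 ± 38.4 (SD, n = 3 each; log2 fold change 1.78, SE 0.157). CDCA7 rose by 0.96 (SE 0.0773), CDT1, a replication licensing factor, by 0.75 (SE 0.104) and the helicase subunit MCM5 by 0.60 (SE 0.0727).

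G1 cyclins and CDK inhibitors were not called as a list. Of 11 tested, 4 rose, 3 fell and 4 did not pass, and adjusted over the list alone 6 rose and 4 fell; the median log2 fold change was 0.20, the mean -0.04, and camera gave an adjusted p of 0.943. CCND3, the cyclin D of many lymphoid cells, fell from 5471 ± 374 to 1649 ± 15.96 (SD, n = 3 each; log2 fold change -1.73, SE 0.0692). With the median of its probe sets the log2 fold change was -0.56 (adjusted p = 0.0462, within 1.2e-11 to 0.0462 over all alternatives). CDKN1B, which encodes the CDK inhibitor p27, rose from 379 ± 33.2 to 1114 ± 128 (1.55, SE 0.102). FOXO targets likewise went both ways: of 16 tested, 6 rose, 7 fell and 3 did not pass, with 6 and 7 when adjusted over the list alone, a median of 0.03, a mean of -0.03 and a camera adjusted p of 0.513. The list median lay within -0.491 to 0.185 over all alternatives, and none of them called the list. TXNIP and CCNG2 are among the FOXO targets that rose, and GADD45A, a stress-induced growth arrest gene, fell by 2.30 (SE 0.0913).

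**Figure D3:**
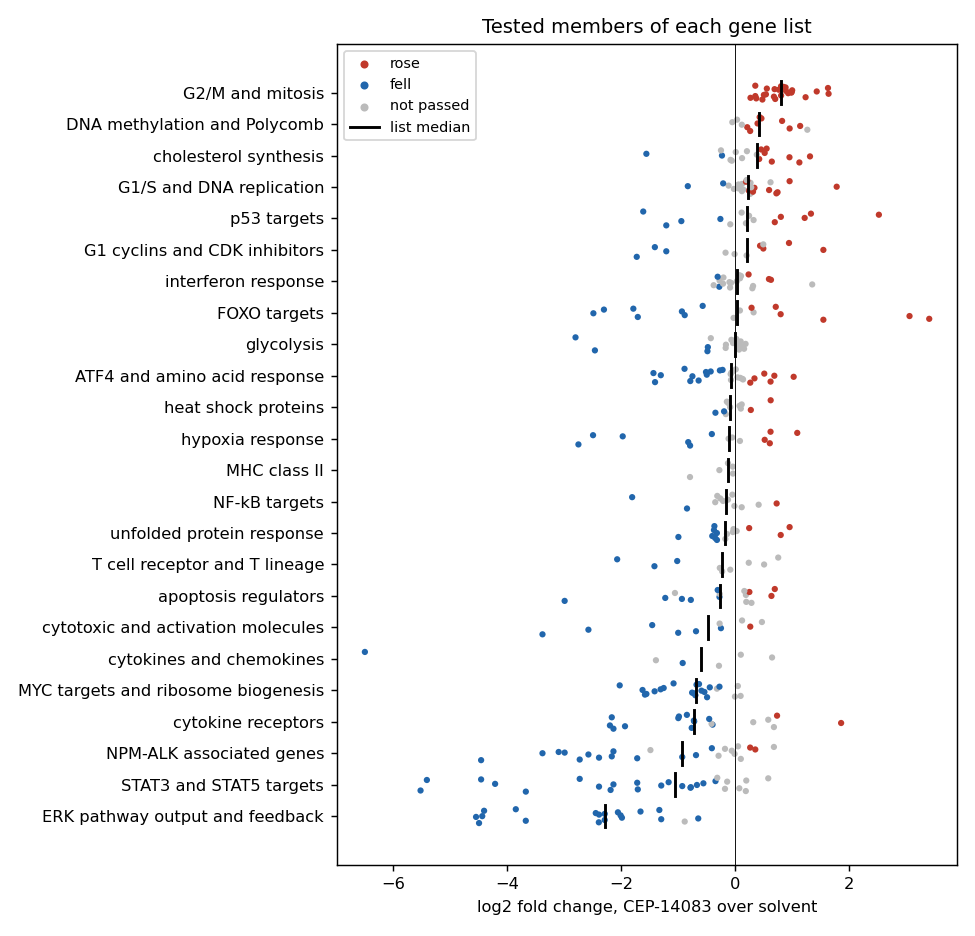
Log2 fold change, CEP-14083 over solvent (horizontal axis), of the tested members of each of the 24 lists with at least 5 tested members (rows, ordered by list median). Points are genes, red for rose, blue for fell and grey for not passed, and a black bar marks the list median, which runs from -2.29 for the ERK list to 0.81 for the G2/M list.

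The glycolysis genes that fell were a glucose transporter, a pair of hexokinases and a phosphofructokinase. Of 18 tested, 4 fell, 0 rose and 14 did not pass, with 4 falling when adjusted over the list alone. SLC2A3, the glucose transporter GLUT3, fell from 2685 ± 187 to 384 ± 29.5 (SD, n = 3 each; log2 fold change -2.80, SE 0.0853). The hexokinases HK2 and HK1 fell by 2.46 (SE 0.16) and by 0.49 (SE 0.0876), and PFKP, the phosphofructokinase, fell by 0.48 (SE 0.0769; adjusted p = 0.468 with the median of its probe sets, within 2.8e-05 to 0.595 over all alternatives). The list median was -0.01 and the mean -0.35 (camera adjusted p = 0.0451; adjusted p = 0.571 with an estimated correlation). The call ended under 7 alternatives, including the removal of solvent control 2 (0.193) or CEP-14083 array 1 (0.0555), the median of probe sets (0.0788) and no intensity trend (0.0705), within 0.0059 to 0.571 over all alternatives, and with arrays centred on their medians the list median was 0.13.

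Hypoxia response genes were divided, with 6 of 13 falling, 4 rising and 3 not passing, and the same numbers when adjusted over the list alone. The median log2 fold change was -0.11 (camera adjusted p = 0.0423; adjusted p = 0.206 with an estimated correlation). PFKFB3, an activator of glycolysis, fell from 2460 ± 180 to 366 ± 46.6 (SD, n = 3 each; log2 fold change -2.75, SE 0.0987). ANKRD37 and NDRG1 fell by 2.49 (SE 0.178) and by 1.97 (SE 0.0881), whereas KDM3A, a histone demethylase, rose by 1.09 (SE 0.0809). The call ended under 6 alternatives, including the median of each gene's probe sets (0.264) and the removal of less specific probe sets (0.473), within 0.0067 to 0.473 over the alternatives that use camera (9.6e-05 with fry, which tests against no change and not against other genes), and with arrays centred on their medians the list median was 0.02.

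Cholesterol synthesis was not called, with 8 of 17 members rising, 2 falling and 7 not passing, 8 rising and 3 falling when adjusted over the list alone, a median of 0.38 and a camera adjusted p of 0.12. The adjusted p was 0.0225 with no filter and 0.0323 without less specific probe sets, within 0.0225 to 0.518 over the alternatives that use camera, and fry, the test against no change, gave 0.0216. HMGCS1, which makes the HMG-CoA of the mevalonate pathway, rose by 1.13 (SE 0.0806), and HSD17B7, a later enzyme of the pathway, fell from 4820 ± 324 to 1634 ± 42.7 (SD, n = 3 each; log2 fold change -1.56, SE 0.0699). The HSD17B7 value came from a less specific probe set, and the gene was not tested without such probe sets.

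The list of ATF4 targets and amino acid response genes had 12 of 27 members falling, 6 rising and 9 not passing, and the same numbers when adjusted over the list alone. Its median log2 fold change was -0.07 (camera adjusted p = 0.0262; adjusted p = 0.384 with an estimated correlation). The adjusted p was 0.0534 without solvent control 2, 0.0602 after quantile normalisation and 0.238 without less specific probe sets, within 0.0109 to 0.384 over the alternatives that use camera (0.0105 with fry, the test against no change), and with arrays centred on their medians the list median was 0.06 (adjusted p = 0.117). The amino acid transporters SLC1A5 and SLC7A5 fell by 1.43 (SE 0.0872) and by 1.30 (SE 0.104) on the log2 scale. ATF3, a stress-induced transcription factor, fell from 1069 ± 153 to 401 ± 23.7 (SD, n = 3 each), and SESN2, an inhibitor of mTORC1, fell by 0.75 (SE 0.0904).

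Other stress programs were not called. Of 15 unfolded protein response genes 3 rose, 7 fell and 5 did not pass, with the same numbers adjusted over the list alone, a median of -0.17 and a camera adjusted p of 0.0822, which was 0.038 without solvent control 3 and lay within 0.038 to 0.527 over all alternatives. XBP1, a transcription factor of that response, fell by 1.00 (SE 0.101), or by 0.29 with the median of its probe sets (adjusted p = 0.274, the highest over its alternatives, whose lowest was 9.2e-07). EDEM1, a degradation factor of the endoplasmic reticulum, rose by 0.96 (SE 0.101). Of 11 heat shock proteins 2 rose, 2 fell and 7 did not pass, the same adjusted over the list alone, with a median of -0.09, a mean of 0.01 and a camera adjusted p of 0.513. DNAJB1 fell by 0.35 (SE 0.0693), and HSPB1 rose by 0.28 (SE 0.0798) with an adjusted p of 0.0156, which was 0.0697 without CEP-14083 array 3, 0.0926 without the intensity trend, 0.103 without variance moderation and 0.0768 with tested-gene medians centred, and lay within 0.0021 to 0.506 over all alternatives.

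Cytokine receptors were called downward as a list. Of 18 tested members 12 fell, 2 rose and 4 did not pass, with the same numbers when adjusted over the list alone. The receptors had a median log2 fold change of -0.72 (camera adjusted p = 9.2e-06; adjusted p = 0.0801 with an estimated correlation). IL2RA, the alpha chain of the interleukin 2 receptor, fell from 3809 ± 249 to 866 ± 64.2 (SD, n = 3 each; log2 fold change -2.14, SE 0.0788, -2.80 with the median of its probe sets and -3.46 without less specific ones). IL6R, IL1RAP and IL4R, subunits of the receptors for interleukins 6, 1 and 4, had log2 fold changes of -2.20 (SE 0.0906), -2.17 (SE 0.105) and -1.93 (SE 0.105). IL2RA and IL1RAP are also members of the NPM-ALK list, so these lists are not independent.

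Cytotoxic and activation molecules, which this lymphoma shares with killer T cells, were called downward too. Of 10 tested members 6 fell, 1 rose and 3 did not pass, with the same numbers when adjusted over the list alone. The median log2 fold change was -0.48 (camera adjusted p = 0.0005; adjusted p = 0.0797 with an estimated correlation). PRF1, which encodes perforin, fell from 5749 ± 243 to 964 ± 58.0 (SD, n = 3 each; log2 fold change -2.58, SE 0.0711). The granzymes GZMA and GZMB fell by 1.00 (SE 0.0702) and by 0.69 (SE 0.0634), and TNFRSF8 belongs to this list as well. PRF1, GZMB and TNFRSF8 are also members of the NPM-ALK list, so these lists overlap.

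Cytokines and chemokines were not called: 2 of 6 tested fell, 0 rose and 4 did not pass, with the same numbers adjusted over the list alone, a median of -0.60 and a camera adjusted p of 0.069. That adjusted p was 0.0344 without CEP-14083 array 1 and 4.4e-07 with arrays centred on their medians, within 4.4e-07 to 0.424 over the alternatives that use camera, against 0.0199 with fry. Beside CCL20, IL26 fell by 0.92 (SE 0.157). The T cell receptor and T lineage list had 9 tested members, of which 3 fell, 0 rose and 6 did not pass, also when adjusted over the list alone, with a median of -0.23 and a camera adjusted p of 0.0552. It was 0.0489 with the replicate block, 0.0373 without solvent control 1, 0.0461 without CEP-14083 array 1 and 0.0441 and 0.045 with pseudocounts of 16 and 64, within 0.0373 to 0.216 over the alternatives that use camera, against 0.0012 with fry. Of its members, 14 lay under the filter, with signals of 0.3 to 36.6 on single arrays over all their probe sets. GATA3 and LEF1, transcription factors of T cell development, fell by 2.07 (SE 0.252) and by 1.02 (SE 0.0857), and the adjusted p of LEF1 was 0.0593 with the median of its probe sets, within 1e-07 to 0.0603 over all alternatives.

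Apoptosis regulators were not called, with 6 of 15 falling, 3 rising and 6 not passing, the same adjusted over the list alone, a median of -0.27 and a camera adjusted p of 0.0635. The adjusted p was 0.0313 without CEP-14083 array 1, within 0.0313 to 0.238 over the alternatives that use camera, and fry gave 0.00033. MCL1, an anti-apoptotic protein like BCL2A1, fell from 2711.5 ± 63.6 to 1582 ± 49.8 (SD, n = 3 each; log2 fold change -0.78, SE 0.0654), with an adjusted p of 0.156 without less specific probe sets, within 2.1e-07 to 0.226 over all alternatives. Among 14 p53 targets 5 rose, 4 fell and 5 did not pass, the same adjusted over the list alone, with a median of 0.22 and a camera adjusted p of 0.887. CDKN1A, which encodes the CDK inhibitor p21, fell by 1.21 (SE 0.0869), and DDB2, a DNA damage recognition protein, rose by 1.33 (SE 0.101). Of 12 NF-kB targets 1 rose, 2 fell and 9 did not pass, the same adjusted over the list alone, with a median of -0.17 and a camera adjusted p of 0.149. ICAM1, an adhesion molecule, fell by 1.81 (SE 0.149) and NFKBIA, the inhibitor of NF-kB, fell by 0.84 (SE 0.0977).

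The DNA methylation and Polycomb list was called upward. Of 12 tested members 8 rose, 0 fell and 4 did not pass, and 9 rose when adjusted over the list alone. The median log2 fold change was 0.41 (camera adjusted p = 0.0037; adjusted p = 0.349 with an estimated correlation), and the adjusted p was 0.0501 with the median of each gene's probe sets, within 2.4e-05 to 0.349 over all alternatives. TET2, which oxidises methylated cytosine, rose from 184.5 ± 16.2 to 408 ± 9.27 (SD, n = 3 each; log2 fold change 1.14, SE 0.111). DNMT3B, a DNA methyltransferase, rose by 0.96 (SE 0.122), and the Polycomb subunits EZH2 and SUZ12 rose by 0.83 (SE 0.0938) and by 0.46 (SE 0.066). With the median of their probe sets, the log2 fold change of TET2 was 0.33 (adjusted p = 0.61, within 7.3e-07 to 0.61 over all alternatives), and the adjusted p of SUZ12 was 0.136, within 4.5e-05 to 0.281.

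The interferon response list was not called: of 19 tested members 3 rose, 2 fell and 14 did not pass, the same adjusted over the list alone, with a median of 0.03, a mean of 0.10 and a camera adjusted p of 0.705 in the downward direction. IFIH1, a sensor of viral RNA, rose by 0.63 (SE 0.142). GBP1, a guanylate-binding protein, rose by 0.60 (SE 0.141, adjusted p = 0.005), and its adjusted p was 0.0734 with the median of its probe sets, 0.0752 without less specific probe sets and 0.0623 without variance moderation, within 0.0031 to 0.101 over all alternatives. None of 5 MHC class II genes passed over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05 in limma; median -0.12, camera adjusted p = 0.513). CIITA, the activator of those genes, read 33.5 ± 9.44 in solvent and 20.9 ± 12.98 with CEP-14083, and HLA-DQB1 read 30.4 ± 6.09 and 25.3 ± 6.56 (SD, n = 3 each).

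Marker lists of other cell types held 1 to 4 tested members each and were given no list test. The members under the filter numbered 4 for B cells, 3 for myeloid cells, 4 for erythroid cells, 6 for fibroblasts and 6 for epithelium, with signals on single arrays of 0.4 to 30.6, 0.6 to 55.8, 1.2 to 56.7, 0.4 to 47.4 and 0.9 to 42.9 over all their probe sets. Of 3 B cell markers 0 passed, and 0 had an unadjusted p under 0.05 in limma. CD22 read 36.6 ± 18.2 in solvent and 20.5 ± 8.38 with CEP-14083, and CD79B read 47.3 ± 35.3 and 32.5 ± 21.6 (SD, n = 3 each). Of 4 myeloid markers 3 fell and 1 rose, also when adjusted over the list alone. FCER1G, a signalling chain found in many blood cells, fell from 5116 ± 312 to 3108 ± 110 (log2 fold change -0.72, SE 0.0688), and S100A8 rose from 246 ± 60.9 to 374 ± 34.3 (0.63, SE 0.155), with an adjusted p of 0.0533 without the intensity trend and 0.109 without variance moderation, within 0.00018 to 0.109 over all alternatives. The erythroid marker HBB did not pass and read 30.3 ± 20.7 and 25.1 ± 6.14. Neither fibroblast marker passed, nor had an unadjusted p under 0.05. The fibroblast markers COL1A1 and COL1A2 read 37.2 ± 20.9 and 27.8 ± 27.4 in solvent, and 64.2 ± 22.5 and 31.1 ± 7.97 with CEP-14083, and with the median of its probe sets COL1A1 had an adjusted p of 0.0091, within 0.0091 to 0.452 over all alternatives. Of the 2 epithelial markers tested, KRT18 rose from 172 ± 36.9 to 257 ± 27.2 (0.60, SE 0.167, adjusted p = 0.0126), and its adjusted p was 0.0603 without CEP-14083 array 3, 0.0599 without the intensity trend and 0.118 without variance moderation, within 0.0076 to 0.118 over all alternatives.

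Control probe sets at both ends of a transcript were compared as a sign of RNA quality. The log2 ratio of 3' to 5' signal was 0.37 ± 0.03 in solvent and 0.43 ± 0.06 with CEP-14083 for beta-actin (SD, n = 3 each; two-sided exact permutation p = 0.2), and -0.13 ± 0.02 and -0.14 ± 0.04 for GAPDH (p = 0.9, n = 3 each, exact permutation), so the groups differed by 0.06 and -0.01. The smallest p that 3 against 3 arrays allow is 0.1. The first principal component held 56.7% of the variance and separated the groups, and the second held 22.3% and separated solvent control 3 from solvent controls 1 and 2. The array numbers did not pair the arrays, since deviations from the group means correlated at -0.05, 0.02 and -0.02 across probe sets, which are not independent replicates, between arrays of the same number, and a fit with a replicate block gave 4325 changed genes.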

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

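Apart from the count over other splits of the arrays, the tests in this part were chosen after the results they weigh were seen.

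The control probe sets for ribosomal RNA lie outside the comparison of genes, and 2 of the 6 were higher with CEP-14083 than in solvent on every array. The middle part of 28S read 2020 ± 336 in solvent and 5631 ± 809 with CEP-14083 (SD, n = 3 each), a log2 difference of 1.48, and its 5' part read 547 ± 26.2 and 1196 ± 83.4, a log2 difference of 1.13. Both had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. The 3' part of 28S, at the floor with 22.7 and 19.7, had a log2 difference of 0.05 (exact p = 0.9), and the 3 parts of 18S had 0.71, 0.44 and 0.01 (exact p = 0.3, 0.4 and 1). RNA degradation is argued against, since the 3' to 5' log2 ratio of beta-actin differed by 0.056 (SE 0.037) between the groups. Carry-over of ribosomal RNA of every kind into the labelled sample stays open, since the 18S probe sets differed by 0.385 (SE 0.577), against 1.30 (SE 0.115) for 28S without its 3' part and 0.885 (SE 0.378) with it, and solvent control 3 alone moved the 18S difference from 0.889 to that value. A treatment effect on ribosomal RNA or its adenylation stays open as well and was not tested, since labelling starts from poly(A) and the arrays cannot tell the amount of ribosomal RNA from the part of it that was primed.

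Probe sets without a single gene symbol took no part in the count of genes. Of 27281 probe sets past the filter 5072 were of this kind, and 1103 of them passed the threshold between CEP-14083 and solvent, with 658 rising and 445 falling.

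The G2/M and mitosis list rose in all 25 tested members, with a median log2 fold change of 0.81. A shift of whole arrays in scale, of the size seen in all tested genes (median 0.096), is argued against as the whole cause. After each array was centred on its median over the tested genes, the list median was 0.702 (SE over genes 0.094). That centring moves every gene alike, so a larger shift was not tested. Solvent control 3 alone is argued against too, with a median of 0.746 without it. A larger share of cells in G2 and M after 6 h may account for the rise and stays open. The list lay 0.58 above the G1/S list (SE 0.15 over genes taken as independent, not between arrays). But 10 of 26 members of the G1/S list rose too, with a list median of 0.23, or 0.19 without solvent control 3. An estimated correlation ended the camera calls of both lists (adjusted p = 0.14 for G2/M and 0.373 for G1/S). No measure of cell cycle phase was analysed here. A change of transcription of the G2/M genes at a constant share of cells cannot be told apart from a larger share with these arrays.

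More genes rose than fell, 61.8% of those that passed. Solvent control 3 alone is argued against, since the share was 60.1% without it. The choice of a scaling factor for each array could account for the excess: the share was 47.5% after centring on tested-gene medians and 66% after centring on medians over all probe sets. Centring on tested genes draws the share towards equal numbers by construction, and no measure of total RNA per cell was analysed here, so scaling and a true excess of rising genes cannot be told apart. For the count itself, 1 of the 10 splits of the 6 arrays, the real one, gave 4381 genes, and the highest of the others gave 0; with 10 splits a share under 0.05 cannot be reached.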

How the results depend on the processing

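The scalings by tested-gene medians and by cyclic loess were chosen after seeing the data. Over 19 alternatives, the count of changed genes stayed within 1.5 times of 4381 except with arrays centred on their medians over all probe sets, where 1375 passed, 908 rising and 467 falling. That centring uses probe sets at the floor, where solvent control 3 read higher (median deviation 1.33 log2 for probe sets under a mean log2 of 3, against -0.13 for those above 8). With each array left out in turn, 3438 to 4730 genes passed. Changes of at least 2-fold numbered 573 with the stricter filter, where 7511 genes were tested, and 445 with a pseudocount of 64, which shrinks folds by construction. Camera called 10 to 14 lists with arrays left out and 1 with an estimated correlation, and fry, a different test, called 16.

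Of 83 named genes, 57 kept their direction and their side of the threshold under every alternative in which they were tested. Of the other 26, 20 no longer passed with arrays centred on their medians and 6 with the median of probe sets, which overlap. Directions turned only in CD79B (-1.03 to 0.137 with arrays left out), COL1A2 (-0.30 to 1.15) and HBB (-0.386 to 0.261, and 0.0298 with arrays centred on their medians), none of which passed. An alternative that dropped a gene was not counted for it. MYC, for example, was tested in 18 of 19 alternatives and SEMA3C in 17. Ranges given over all alternatives leave out the missing ones too.

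Of 24 lists, 5 kept camera's direction and call in every alternative in which they were tested. They were the called ERK list and the uncalled FOXO, heat shock, MHC class II and NF-kB lists. The MHC class II list was tested in 18 alternatives and the ERK list in 20. The 11 other called lists lost their call with an estimated correlation. Camera's direction, taken relative to the other genes, turned in 3 uncalled lists. Their list medians, in brackets, were positive in the main fit and stayed positive where the direction turned. For G1 cyclins and CDK inhibitors it turned with no filter (0.301), the stricter filter (0.321) and the median of probe sets (0.135). It also turned without less specific probe sets (0.389), without solvent control 1 (0.186) and without CEP-14083 array 1 (0.324). With each array left out in turn, whether or not the direction turned, the list median lay within 0.149 to 0.324. For the interferon response it turned with arrays centred on their medians (0.161) and the median of probe sets (0.104). It also turned without less specific probe sets (0.171) and without solvent control 3 (0.0493), and fry's own direction was upward (0.0298). Over all arrays left out in turn, that list's median lay within -0.164 to 0.0493, and the direction turned only without solvent control 3. For p53 targets it turned with quantile normalisation (0.13), the stricter filter (0.153) and without CEP-14083 array 1 (0.202) or 2 (0.138). Over all arrays left out, the median of the p53 list lay within 0.138 to 0.209. The cause was not tested. No detection calls were used here, so for genes with signals near the floor the arrays cannot tell expression from background.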

Other observations

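The gene families and single genes here were chosen after their values were seen, so their tests describe and do not test a prediction. Metallothioneins, which bind zinc and other metals, rose in 5 of 7 tested genes and fell in 0, with a median log2 fold change of 1.90 (camera adjusted p = 0.00011; adjusted p = 0.19 with an estimated correlation). MT2A read 604 ± 68.7 in solvent and 2281 ± 458 with CEP-14083 (SD, n = 3 each), and MT1X read 284 ± 45.8 and 1194 ± 177. Aldo-keto reductases of the AKR1 family rose in 3 of 4 tested genes (median 2.23; camera adjusted p = 0.0066; adjusted p = 0.194 with an estimated correlation), with log2 fold changes of 2.42 for AKR1C1, 2.48 for AKR1C2 and 2.05 for AKR1C3. Members of both families are close in sequence, so probe sets of different members can bind the same transcript. SQSTM1, an autophagy receptor, rose from 498 ± 109 to 1940 ± 105. The 3 tested YPEL genes all rose, YPEL1 by 2.91, YPEL2 by 1.66 and YPEL5 by 1.34 (camera adjusted p = 0.003; adjusted p = 0.19 with an estimated correlation). The value of YPEL1, whose solvent signals lay near the floor, was 2.00, 1.73 or 2.24 without solvent control 1, 2 or 3, 2.28 without CEP-14083 array 3, 2.27 after quantile normalisation and 1.85 with the median of its probe sets.

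Receptors of the TNF receptor superfamily fell in 8 of 12 tested genes and rose in 0 (median -0.87; camera adjusted p = 2.3e-06; adjusted p = 0.175 with an estimated correlation). Beside TNFRSF8, TNFRSF21 read 2215 ± 135 in solvent and 176 ± 35.4 with CEP-14083 (SD, n = 3 each), and TNFRSF10D, a decoy receptor of the death ligand TRAIL, read 1418 ± 48.2 and 200 ± 11.7. Subunits of RNA polymerases I and III fell in 10 of 18 tested genes and rose in 1 (median -0.62; camera adjusted p = 4.9e-05; adjusted p = 0.19 with an estimated correlation), with log2 fold changes of -1.49 for POLR1G and -1.49 for POLR3G. RNA45SN5, the precursor of ribosomal RNA, read 152 ± 52.2 and 1169 ± 134, and the 45S probe sets differed by 2.52 (SE 0.215) on the log2 scale, for which carry-over of ribosomal RNA was not excluded. ALKAL2, which encodes a ligand of ALK, fell from 1119 ± 64.7 to 244 ± 14.4. MAP3K5, the gene opposite the antisense transcript MAP3K5-AS1, rose from 130 ± 22.5 to 385 ± 35.4 (log2 fold change 1.57, SE 0.147).

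Lysine demethylases and methyltransferases rose in 14 of 25 tested genes and fell in 1 (median 0.47; camera adjusted p = 0.0016; adjusted p = 0.19 with an estimated correlation), among them KMT2E (log2 fold change 1.48). Kinesins rose in 19 of 32 and fell in 2 (median 0.58; camera adjusted p = 0.00047; adjusted p = 0.19 with an estimated correlation), and share members such as KIF20A with the G2/M list. Histone genes rose in 8 of 25, or 13 without solvent control 3 and 4 with arrays centred on their medians, and fell in 0 (median 0.53; camera adjusted p = 0.0201; adjusted p = 0.19 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.16 over 53 genes, with 5 rising and 1 falling (camera adjusted p = 0.0035; adjusted p = 0.586 with an estimated correlation). The numbers depended on single arrays and on scaling. Without solvent control 3, 2 rose, without solvent control 2, 42 rose, and without any other single array 0 rose. After centring on tested-gene medians 0 rose and 1 fell, and with cyclic loess 38 rose and 1 fell. Of 286 numbered zinc finger genes 65 rose and 26 fell (camera adjusted p = 0.35), and 39 to 76 rose with arrays left out. With arrays centred on their medians over all probe sets each family median moved up by 0.131 and fewer members passed in some families: 9 kinesins (median 0.71), 9 lysine enzymes (0.60) and 26 zinc finger genes (0.32) rose, and 5 TNF receptors (-0.74) and 5 polymerase subunits (-0.49) fell. For the families named here the sign of the median was the same under the 4 other scalings run and with each array left out.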
